A study of Mus musculus with 6 samples.

How the data were processed

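RNA was sequenced from haematopoietic stem cells of C57BL/6 mice, 3 libraries from Hlf knockout animals and 3 from wild-type littermates. Per the labels' protocols, each library came from 3000 freshly sorted cells that were lineage-negative, Sca-1-positive, c-Kit-positive, CD34-negative and Flt3-negative, and was made from total RNA with an Illumina TruSeq kit. The labels number the libraries 1 to 3 within each genotype and do not say whether each came from its own animal, so p-values measure the spread between these libraries, which may be partly technical.

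The authors deposited whole-number read counts per RefSeq transcript, not normalised. Per the submitters' processing notes, TopHat and the mouse build mm9 were used. The TopHat version, the counting tool, the annotation release, the use of strand and the treatment of reads shared by several transcripts are not given in the sources used here. Each library listed the same 30858 transcripts, and 0 columns were left unmatched to a sample. Gene symbols came from a RefSeq gene table of assembly GRCm38.p6 for 30363 transcripts and from GENCODE cross-references for 179 more, while 316 kept their accession as a name. Because the builds differ, no coordinates are printed. Counts were summed per gene, which gave 23574 features, 4236 of them with several listed transcripts.

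The counting limits which genes can be measured. Genes with 1 listed transcript had a median of 86 counts over the 6 libraries, against 3 for genes with 2 transcripts and 2 for genes with 3 or more, and genes with 1 transcript held 96.9% of all counts. A low count of a gene with several transcripts is therefore not read as low expression. Genes of the sort were affected. Kit, with 2 transcripts, had 1 count in total, Ly6a (Sca-1), with 6, had 0, and Cd34, with 2, had 24, so these 3 genes were not tested.

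Differential expression used edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr by genotype (minimum count 10, minimum total 15), and the robust quasi-likelihood F test of knockout against wild type over all 6 libraries without covariates. P-values were adjusted by the Benjamini-Hochberg method over 10204 tested genes, and an adjusted p under 0.05 counted as a change. Standard errors of log2 fold changes were taken from the F statistic. CPM values are counts scaled by library size and TMM factor, and log2 CPM used a prior count of 2. Hlf was also compared by a two-sided exact permutation test of log2 CPM, for which 3 libraries against 3 give no p below 0.1.

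Of 29 gene lists, 28 had at least 3 tested members and were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 28 lists. The same lists were tested with camera's estimated correlation and with fry. They covered stem cell identity, restraint of the cell cycle, DNA replication, mitosis, and the cyclins, kinases and transcription factors of early cell cycle entry. They also covered PAR bZIP and clock genes, the Bcl2 family, p53 targets, antioxidant enzymes, hypoxia and glycolysis, oxidative phosphorylation and ribosomal proteins. Others held granulocyte-monocyte, megakaryocyte, erythroid and lymphoid genes, surface genes of multipotent progenitors, interferon-stimulated genes, immediate early and heat shock genes, TGF-beta signalling, and genes near Hlf. The last set marked B cells, T cells, granulocytes, macrophages, endothelium, stroma, mast cells and basophils, and the sex of the donor.

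Named genes followed a rule. They are Hlf and, per direction, 12 genes with a mean log2 CPM of at least 2 and no overlap between genotypes, first those with an adjusted p under 0.05 by size and then those of smallest p, together with the 4 members of smallest p in each list and the genes of the sort. An item that this rule names is not reported here. The tests, samples, lists, naming rule and most alternatives were fixed before the data were examined.

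Counts were simulated for 10204 genes from these libraries' means, sizes and spread. The 200 changed genes were drawn from those with a mean log2 CPM of at least 4, so recovery of weaker genes was not measured. Of these, edgeR recovered 6% of genes changed 2-fold, 58% of those changed 4-fold, 80% at 8-fold and 86% at 16-fold. Of its 123 calls, 8 were false. DESeq2 1.42.0 recovered 18%, 74%, 84% and 94%, and 51 of its 186 calls were false. With no simulated change edgeR made 0 calls and DESeq2 made 3. A simulated rise of 0.6 log2 units in the DNA replication list was called by camera with the preset correlation (adjusted p = 5.1e-05) and missed with an estimated one (adjusted p = 0.197). The preset correlation also called 1 of the other lists, macrophages, which held 0 of the raised genes, and the estimated one called 0. With no simulated change the preset correlation called 0 lists. The simulated genes varied independently of each other. In the real libraries the estimated correlation was 0.115 for replication, 0.180 for mitosis and 0.488 for granulocyte-monocyte genes, though -0.218 for B lymphoid genes. These runs therefore cannot show how either setting behaves where list members vary together.

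Total counts ran from 8346335 to 11998296 per library, so that 3 counts correspond to 0.250 to 0.359 CPM. Libraries were checked for repeats: no pair agreed within sampling noise, with chi-square per degree of freedom of at least 56.5 over genes with 20 or more counts in both. Alternatives covered other scaling factors, DESeq2, limma-voom, filters on low counts, the robust option, a threshold of 0.1, the replicate number as a block, and leaving out each library. Alternatives added later were a sex covariate, library quality weights, transcripts left unsummed, genes with 1 transcript, list members with a mean log2 CPM of at least 4, and libraries thinned to the smallest total. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.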

Results

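Gene expression was measured by RNA sequencing in haematopoietic stem cells sorted from mice that lack Hlf (hepatic leukaemia factor, a transcription factor of the PAR bZIP family) and from wild-type littermates. The question was which genes differ between knockout and wild-type stem cells, with restraint of the cell cycle as the process of interest. Each genotype had 3 libraries of 3000 sorted cells. The wild-type libraries 1, 2 and 3 held 8346335, 9902102 and 8800688 counts, and the knockout libraries 10462713, 10182464 and 11998296, so every knockout library was deeper than every wild-type one. At least 1 count was seen for 10796, 11341 and 12331 features in the wild-type libraries and for 12207, 12097 and 12133 in the knockout libraries.

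The libraries varied more within the wild type than within the knockout. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.749 to 0.805 between wild-type libraries, 0.869 to 0.883 between knockout libraries and 0.776 to 0.848 between genotypes. The biological coefficient of variation estimated by edgeR was 80.4% in wild type and 54.3% in knockout. The first principal component, with 36.4% of the variance, set wild-type library 1 apart, and the next, with 24.5%, set wild-type library 2 apart. Xist was abundant in 1 library of each genotype, wild-type library 3 with 16730 counts and knockout library 3 with 19229, and at most 34 counts were seen in any other.

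Hlf fell in the knockout. It stood at 1382.1 ± 274.2 CPM in wild type (SD, n = 3) and at 34.4 ± 5.30 CPM in knockout (SD, n = 3), where 2.49% of the wild-type level was left. The raw counts were 10768, 15982 and 10055 in wild-type libraries and 309, 399 and 431 in knockout libraries. The log2 fold change was -5.33 (SE 0.26), or 40.2-fold lower with a 95% interval of 28.2 to 57.2 (edgeR adjusted p = 1.9e-06). The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The part of the gene removed in these mice is not given in the sources used here, so the remaining counts were not assigned to exons.

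**Figure D1:**
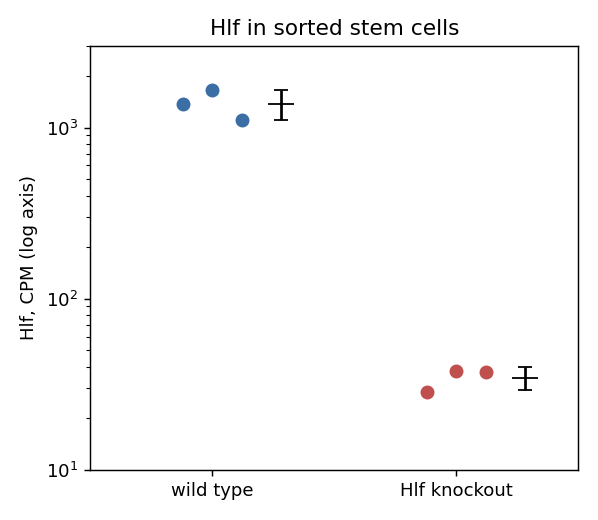
Hlf in TMM-scaled CPM (log axis) in each library, 3 wild-type in blue and 3 knockout in red, with the mean and SD beside each group. The knockout libraries lie near 34.4 CPM and the wild-type libraries near 1382.1 CPM.

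Hlf was the 1 gene of 10204 that changed between genotypes by edgeR's quasi-likelihood test. No gene rose (0 higher), and the next smallest adjusted p was 0.19. At an unadjusted p under 0.05 there were 742 genes, 268 with higher and 474 with lower values in knockout, against 510.2 expected by chance. The genotypes did not overlap for 14.4% of genes, where chance gives 10%. Of these, 767 had higher and 699 lower values in knockout, a balance opposite to that of the unadjusted p-values. DESeq2 called 170 genes, 57 higher and 113 lower, and limma-voom called 1. Without wild-type library 1 edgeR called 3 genes (Hlf, Pf4 and Pou2af1), and without wild-type library 2 it called 2 (Hlf and Jchain). The median standard error of a log2 fold change was 0.59. Simulated 2-fold changes were recovered for 6% of genes, all with a mean log2 CPM of at least 4.

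Among genes with lower values in every knockout library, none besides Hlf passed edgeR's test. Prtn3, which encodes the neutrophil granule protease proteinase 3, had a log2 fold change of -5.07 (SE 0.79, adjusted p = 0.19). Pou2af1, a B-cell transcriptional coactivator, stood at -4.18 (SE 0.83), and Gstm1, a glutathione transferase, at -1.65 (SE 0.32). Wild-type library 3 was the highest for Prtn3 (367.0 CPM) and Pou2af1 (389.2 CPM), and without it their log2 fold changes were -4.12 and -2.57. The long non-coding RNA Malat1 averaged 9290.8 CPM in wild type and 4604.9 CPM in knockout, a log2 difference of -1.01 (SE 0.19, adjusted p = 0.37). Values for Arhgap32, Fmnl2 and Prdm2 were -4.69, -2.78 and -2.05 (Prdm2 -1.32 without wild-type library 1), and those for Fndc3a, Nwd1, Rere and Zfp36 lay between -1.41 and -1.13. All of these 11 genes passed DESeq2's test (largest adjusted p = 0.0108, for Zfp36). Of them, Arhgap32 and Prdm2 have 2 listed transcripts each, a class of genes with low counts here, so their values may not stand for the whole gene.

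Among genes with higher values in every knockout library, Pf4, the platelet chemokine, averaged 132.7 ± 46.4 CPM in wild type and 436.9 ± 77.7 CPM in knockout (SD, n = 3). Its log2 fold change was 1.72 (SE 0.29, edgeR adjusted p = 0.25), and it passed edgeR's test without wild-type library 1 (adjusted p = 0.0142). The thrombin receptor gene F2r stood at 1.18 (SE 0.25). Nkg7 and Ccl5, both known from cytotoxic lymphocytes, stood at 1.64 (SE 0.34) and 2.39 (SE 0.54), Thy1 at 1.53 and Cd180 at 1.86. The others were Mettl6 (2.02), the tubulin gene Tuba8 (1.60), Acadl (1.54), Mfsd2b (1.19), the replicative helicase subunit Mcm3 (0.95) and the condensin subunit Smc4 (0.85). None of these 12 genes passed by edgeR, and 10 passed by DESeq2, the exceptions being Mcm3 and Smc4.

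**Figure D2:**
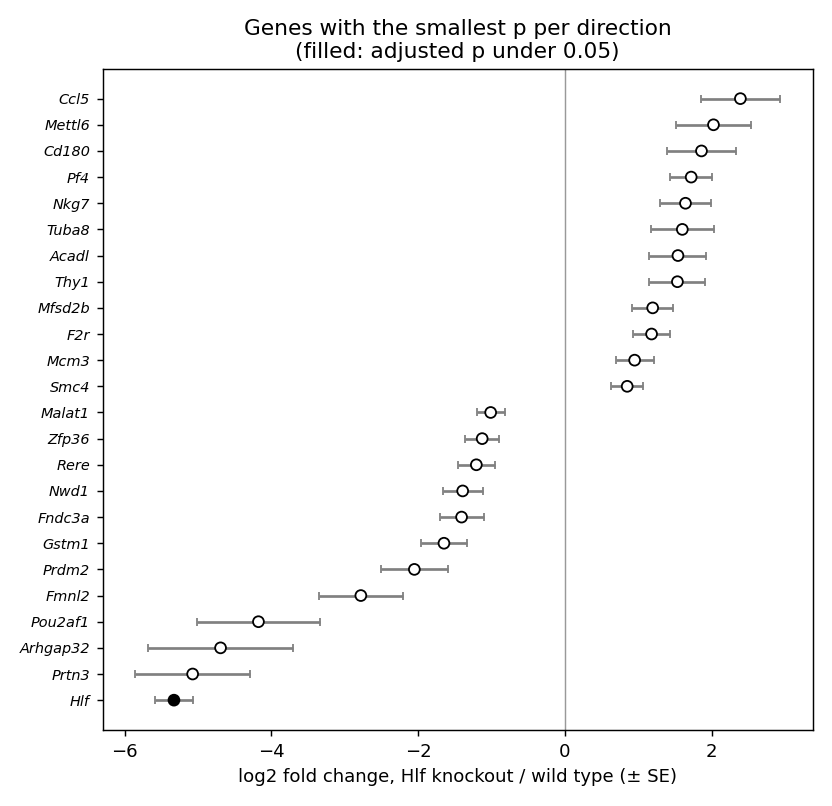
Log2 fold change of knockout over wild type (horizontal axis) with its standard error for 24 genes, 12 per direction. They had the smallest p among genes with a mean log2 CPM of at least 2 whose 3 knockout libraries did not overlap the 3 wild-type libraries. The filled point, Hlf at -5.33, is the gene with an edgeR adjusted p under 0.05, and open points did not pass.

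Of 28 gene lists, 7 were called by camera with a preset correlation, 4 higher and 3 lower in knockout. With an estimated correlation 0 were called (smallest adjusted p = 0.39). The fry test, which compares a list with no change and not with other genes, called 1, the B lymphoid list. In a simulation with 1 list raised, the preset correlation also called 1 list with no raised gene. That simulation used independent genes and does not cover lists whose members vary together. Of the 10 ways to divide the 6 libraries into 3 and 3, 2 gave at least 7 calls. These were the real division and another that mixed the genotypes, with 9 calls. Any or all of the 7 calls may therefore be false. No member of any list passed edgeR's test adjusted over all genes.

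DNA replication genes rose as a set in the knockout. Of 28 tested members 26 had positive log2 fold changes, and the mean log2 CPM was 0.62 higher (camera adjusted p = 0.00024, and adjusted p = 0.39 with an estimated correlation). The helicase subunits Mcm3, Mcm5 and Mcm4 stood at 0.95 (SE 0.26), 0.84 (SE 0.24) and 0.69 (SE 0.24), and the DNA polymerase subunit Pole at 0.80 (SE 0.29). Genes of mitosis rose likewise, with 22 of 26 members positive and a mean difference of 0.71 (camera adjusted p = 0.00039, and adjusted p = 0.40 with an estimated correlation). The spindle checkpoint kinase Bub1b stood at 1.18 (SE 0.32), the spindle motor Kif11 at 0.81 (SE 0.23), Ckap2l at 1.59 (SE 0.62) and Cks2 at 0.77 (SE 0.31, and 0.47 without knockout library 2). At an unadjusted p under 0.05, 7 replication and 6 mitosis genes had higher values and 0 lower ones, and 0 passed in either list when adjusted over the list alone. Every knockout library scored above every wild-type library on both lists. Wild-type library 1, which had the fewest features with a count, was also the lowest on both, at 5.86 for replication and 5.73 for mitosis, against 6.41 and 6.64 in wild-type library 3.

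Nuclear-encoded subunits of oxidative phosphorylation were called higher by camera with the preset correlation. Of 64 members 47 were positive, 3 had an unadjusted p under 0.05, and the mean difference was 0.26 (camera adjusted p = 0.036, and adjusted p = 0.54 with an estimated correlation). Ndufb2 stood at 1.04 (SE 0.44) and Sdha at 0.48 (SE 0.21), both among those 3. Uqcrfs1, at 0.91 (SE 0.42), was not among them (edgeR unadjusted p = 0.0506), and 0 members passed when adjusted over the list alone. The camera call was lost without wild-type library 1 (adjusted p = 0.0991), wild-type library 3 (0.201), knockout library 2 (0.0683) or knockout library 3 (0.202).

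Megakaryocyte and platelet genes were called higher by camera, with 10 of 14 members positive and a mean difference of 0.78 (camera adjusted p = 0.020, and adjusted p = 0.39 with an estimated correlation). Pf4 and Gp1ba, a subunit of the platelet receptor for von Willebrand factor, passed when adjusted over the list alone, 2 members in all. Gp1ba stood at 2.40 (SE 0.67), its partner Gp9 at 1.36 (SE 0.48) and Plek at 0.53 (SE 0.27, and 0.34 without wild-type library 3). The call was lost without wild-type library 3 (adjusted p = 0.292), knockout library 2 (0.0683) or knockout library 3 (0.0916).

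The list of immediate early and heat shock genes fell as a set, though it held only 2 tested heat shock members, with a median log2 fold change of -0.239. Of 16 members 14 were negative, 7 of them with an unadjusted p under 0.05, and the mean difference was -0.64 (camera adjusted p = 0.00039, and adjusted p = 0.39 with an estimated correlation). The AP-1 genes Fos and Fosb stood at -1.10 (SE 0.27) and -1.08 (SE 0.31), with Fos at -0.73 without wild-type library 1, Egr1 at -1.05 (SE 0.30) and the mRNA-decay factor Zfp36 at -1.13 (SE 0.24). When adjusted over the list alone, 7 members passed. The wild-type libraries scored 8.07 to 8.24 and the knockout libraries 7.42 to 7.65.

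Granulocyte-monocyte genes fell by camera, with all 13 tested members negative and a mean difference of -1.35 (camera adjusted p = 0.0053, and adjusted p = 0.59 with an estimated correlation). Prtn3 passed when adjusted over the list alone, 1 member in all, while Ly6c2 stood at -2.40 (SE 0.89), Csf2ra at -1.16 (SE 0.50) and Csf2rb at -1.24 (SE 0.59). Ly6c2 stood at -0.76 without wild-type library 3, and Csf2rb at -0.76 without knockout library 2. Wild-type library 3 decided this value. Its score was 6.37, the other wild-type libraries scored 2.08 and 2.71, and the knockout libraries scored 1.80 to 3.00. Without it the mean difference was -0.02 (adjusted p = 0.788). The call was also lost without knockout library 1 (-0.87, adjusted p = 0.0792), and the difference was -2.06 without wild-type library 1. Wild-type library 3 held 12383 counts of Mpo, 2150 of Elane and 2305 of S100a8, where no other library exceeded 1448, 72 and 179.

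B lymphoid genes fell by camera, with 4 of 10 members tested, all negative, and a mean difference of -3.17 (adjusted p = 0.0053, and adjusted p = 0.39 with an estimated correlation). The fry test against no change gave an adjusted p of 0.015, and the camera call was lost without wild-type library 3 (-3.38, adjusted p = 0.0554). Vpreb1, which encodes part of the surrogate light chain of B-cell precursors, had 58, 265 and 80 counts in wild type and 0, 1 and 0 in knockout, a ratio of 486.3 with a 95% counting interval of 86.8 to 19257 that covers counting error only. Its log2 fold change was -8.40, and -7.55 without wild-type library 2. Vpreb1 was the 1 member that passed when adjusted over the list alone. Igll1 and Vpreb3 stood at -4.06 (SE 2.14) and -2.81 (SE 1.64), and Igll1 at -2.07 without wild-type library 2. Cd79b stood at -0.06 (SE 0.56), and its sign turned under limma-voom.

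**Figure D3:**
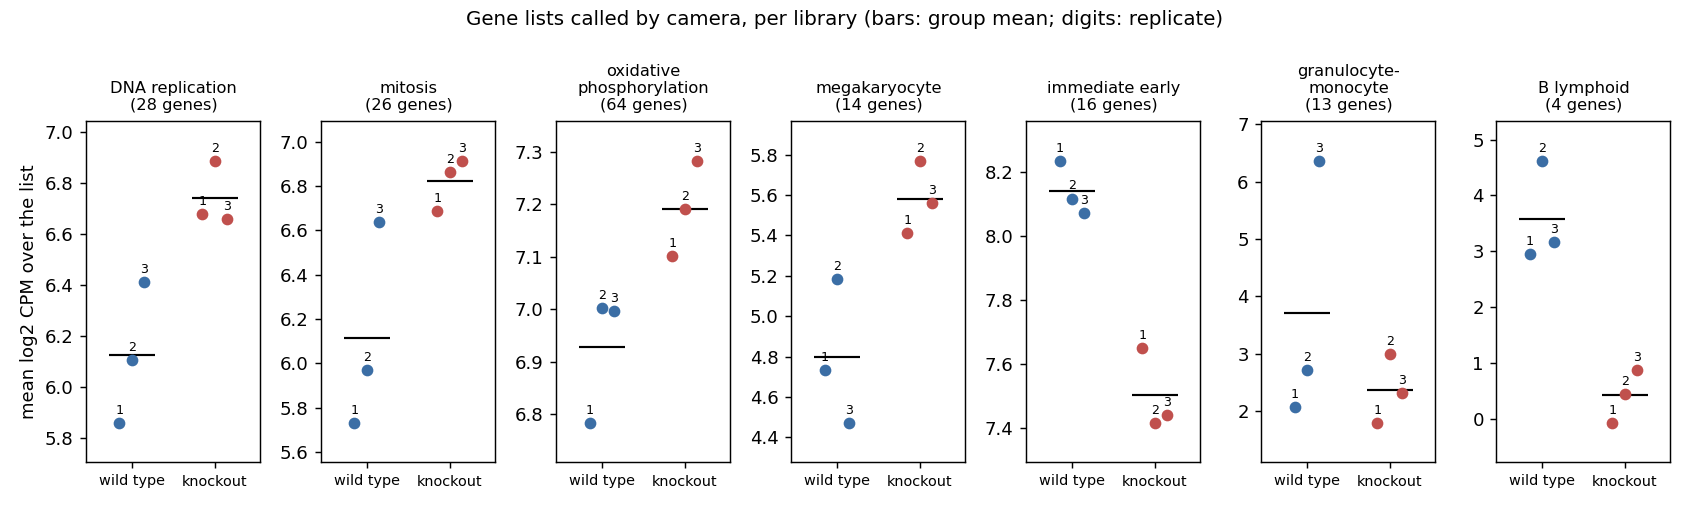
Mean log2 CPM over the tested members of the 7 lists called by camera with a preset correlation, 1 panel per list, with a point for each library (3 wild-type in blue, 3 knockout in red, digits giving the replicate) and a bar at each group mean. The vertical axes differ between panels. Wild-type library 3 lies at 6.37 in the granulocyte-monocyte panel, away from the other 5 libraries.

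Genes of stem cell identity were not called as a list (camera adjusted p = 0.24), and 0 of 30 passed when adjusted over the list alone. Members went both ways, with 13 positive and 17 negative, a pattern that camera, which tests a shift in 1 direction, can miss. The fry test for change in either direction, against no change and not against other genes, gave an unadjusted p of 0.00017. Mycn stood at 1.22 (SE 0.35) and Cavin2 at 1.13 (SE 0.37), while Procr, which encodes the stem cell surface protein EPCR, stood at -1.69 (SE 0.54) and Krt18 at -1.10 (SE 0.38). The list on restraint of the stem cell cycle was not called either (camera adjusted p = 0.46). Egr1 and Mycn, the latter a Myc family factor, were the 2 members that passed when adjusted over the list alone, in opposite directions. Btg1 and Junb stood at -0.75 (SE 0.25) and -1.35 (SE 0.47), with Junb at -0.50 without wild-type library 1. The unadjusted fry p for change in either direction was 0.00054. Among the other lists not called by camera, it was under 0.05 for early cell cycle entry (0.0019), clock genes (0.0018), TGF-beta signalling (0.0098) and genes near Hlf (0.0055).

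The cyclins, kinases and transcription factors of early cell cycle entry were not called (adjusted p = 0.26). Mycn was the 1 member passing when adjusted over the list alone, with E2f3 at 0.98 (SE 0.36) and Cdk6 at 0.74 (SE 0.43, and 0.36 without wild-type library 1). The other PAR bZIP and clock genes were not called (-0.53, adjusted p = 0.12, and adjusted p = 0.39 with an estimated correlation). The difference was -0.78 with the stricter filter on low counts (adjusted p = 0.0326), -0.31 with genes of 1 transcript (0.346) and -0.37 with thinned libraries (0.244). Of these, 5 of 13 had lower values at an unadjusted p under 0.05. Among them were Bhlhe40 at -2.30 (SE 0.78, and -1.49 without wild-type library 3) and Per3 at -1.11 (SE 0.40). Cry2 stood at -1.71 (SE 0.77, and -0.93 without wild-type library 1). Per1, which has 2 listed transcripts, stood at -3.38 (SE 1.18, lower in every knockout library, DESeq2 adjusted p = 0.0057). In this list 0 members passed when adjusted over the list alone. The Bcl2 family (adjusted p = 0.28), in which Mcl1 stood at -0.53 (SE 0.20), and p53 targets (adjusted p = 0.26) had 0 such members. Antioxidant enzymes (0.81), hypoxia and glycolysis genes (0.97), ribosomal proteins (0.88), interferon-stimulated genes (0.53) and TGF-beta signalling (0.26) were not called by camera and had 0 members passing when adjusted over the list alone. In the last, the ligand gene Tgfb1 stood at 1.03 (SE 0.28) and Smad3 at -1.47 (SE 0.58). The Smad3 value came from wild-type library 2 (571.2 CPM, against 97.7 and 119.3 in the other wild-type libraries and 63.9 to 120.9 in knockout), and without it was -0.18.

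Erythroid genes had an adjusted p of 0.066 by camera (0.0483 with the stricter filter, 0.0269 with abundant members only and 0.39 with an estimated correlation), with 12 of 14 members positive and 0 passing when adjusted over the list alone. Gata1 stood at 1.24 (SE 0.44) and Aqp1 at 1.07 (SE 0.42, and 0.68 without wild-type library 1). Lymphoid priming genes (0.46) and surface genes of multipotent progenitors (0.81, with a median of -0.60 and a mean of 0.07 that differ in sign) were not called, and 0 members passed. Flt3, excluded by the sort, stood at -0.69 (SE 0.75, edgeR adjusted p = 0.87), and at -0.17 without wild-type library 2. Among markers of other cells, T cells (0.24), macrophages (0.81, median 0.39 and mean -0.20), endothelium (0.72, median -0.63 and mean 0.07), stroma (0.71, median -0.16 and mean 0.86), mast cells and basophils (0.97, median -0.75 and mean 0.13) and genes of donor sex (0.97, median -0.15 and mean 0.14) were not called by camera. With 1 library left out, the means of all of these but T cells turned sign, from -0.50 to 2.04 for stroma and from -0.68 to 1.18 for endothelium. So did those of the multipotent progenitor genes and of the lymphoid priming genes (-0.24 with all libraries, 0.37 without wild-type library 3). In the lists of other cells and of donor sex, the B lymphoid list aside, 1 member passed when adjusted over the list alone. This was the endothelial scavenger receptor Stab2, at -1.90 (SE 0.57). The T-cell gene Themis, at 3.84, passed by DESeq2 (adjusted p = 0.0145), while Cd4 and Cd3e of the same list stood at -2.17 (SE 1.05) and -1.14 (SE 0.87, and -0.30 without wild-type library 1). The granulocyte list had 1 tested member, S100a8, too few for a list test and for an adjustment over the list alone. S100a8 stood at -5.02 (SE 2.08, edgeR adjusted p = 0.68 over all genes), with 255.4 CPM in wild-type library 3 against 22.8 and 1.25 in the other wild-type libraries and at most 6.97 in knockout, and at -2.06 without wild-type library 3. Genes near Hlf were not called (0.10, with 0.0424 for abundant members only and 0.39 with an estimated correlation), and Stxbp4, at -1.39 (SE 0.33), was the 1 member that passed when adjusted over the list alone.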

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

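The sex covariate, library quality weights, unsummed transcripts, genes with 1 transcript, abundant list members and thinned libraries were chosen after seeing the data. Hlf passed under every alternative run, with a log2 fold change between -5.17 and -5.46. The number of genes changed was 1 with other scaling factors, limma-voom, the stricter filter, the non-robust fit, a threshold of 0.1, unsummed transcripts, genes with 1 transcript and thinned libraries. It was 170 with DESeq2, 9 without a filter on low counts, 2 with the replicate block, 2 with the sex covariate, 3 with quality weights and 1 to 3 when 1 library was left out. The cause was not tested. The replicate numbers showed no clear pairing across genes: deviations of same-numbered libraries correlated at -0.01, -0.02 and 0.02. The largest correlations with other numbers were 0.047, 0.047 and 0.017. With 3 libraries per genotype this cannot exclude that the numbers mark matched libraries. Xist was abundant in library 3 of both genotypes. Under the block 5 lists were called, without oxidative phosphorylation (adjusted p = 0.0785) and megakaryocyte genes (0.0591).

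The 7 list calls became 0 with camera's estimated correlation, 1 with fry, which is no test against other genes, and 3 to 8 when 1 library was left out, with 3 left without wild-type library 3. They became 9 with the stricter filter, which added the clock (adjusted p = 0.0326) and erythroid (0.0483) lists, and 8 of 20 with abundant members, which left the B lymphoid list untested and added the erythroid list (0.0269) and genes near Hlf (0.0424). The replication, mitosis and immediate early lists were called in all 6 fits with 1 library left out. Thinning every library to 8346335 counts left 7 lists. The fold change of Cd79b, -0.06, turned to 0.0592 with limma-voom, 0.0509 with the replicate block and 0.0139 with the sex covariate, and ran from -0.391 to 0.379 with 1 library left out. That of Cd3e, -1.14, turned to 0.639 with quality weights. No scaling moved the median log2 fold change by more than 0.07. Of 1495 alternative values of 79 named genes, 7 turned sign, all of Cd79b or Cd3e, and 41 newly passed, 30 of those with DESeq2. Depth sets a floor of 0.250 to 0.359 CPM for 3 counts.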

Other observations

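The gene-order comparison around Hlf, the plasma cell and eosinophil lists, the choice of Rapgefl1, the splits for edgeR's gene count, the tests that leave out wild-type library 1 or 3, and the erythroid test were chosen after the result was seen. The splits for DESeq2 and the lists, the test on abundant genes, the granule sum and the heat shock test were set before.

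Stxbp4, the gene next to Hlf in RefSeq gene order, averaged 216.2 CPM in wild type and 82.5 CPM in knockout, a log2 difference of -1.39 (SE 0.33). Its edgeR adjusted p was 0.43 over all genes and 0.025 over the 20 tested genes nearest Hlf. No other gene of those 20 had an adjusted p under 0.05 over them, and Mmd, on the other side of Hlf, stood at 0.57 (SE 1.05). Rapgefl1 had 0, 3 and 2 counts in wild type and 382, 64 and 433 in knockout, with a log2 fold change of 7.06 and an edgeR adjusted p of 0.37. It passed by DESeq2 (adjusted p = 4.3e-07) and by edgeR without the filter on low counts.

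Wild-type library 3 held transcripts of several mature cells. Ear1 had 1992 counts there and 0 in each other library, Epx 826 against at most 1, and Prss34 329 against 0. Jchain had 45789 counts there, 15320 and 5405 in the other wild-type libraries and 1073 to 2574 in knockout. The plasma cell list, of which Jchain and Pou2af1 are not members, was lower in knockout by camera at an unadjusted p of 0.023. With an estimated correlation camera's unadjusted p was 0.29. The score of this list was 6.37 in wild-type library 3 against 3.07 to 3.49 in the other 5 libraries. The eosinophil list had 1 tested member, too few for a list test, so the plasma cell p-values were not adjusted over lists.

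The lower granulocyte-monocyte list may come from mature cells in wild-type library 3, although the sort for lineage-negative cells would remove these. Without that library the list differed by -0.0175 (SE 0.47), against -1.35 with it. For the B lymphoid list the same source is argued against, since without that library it still differed by -3.38 (SE 0.88), although the camera call was lost (adjusted p = 0.0554). It rests on 4 genes, mainly Vpreb1, and a biological difference between genotypes stays open and untested.

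The higher replication and mitosis genes could reflect loss of weakly expressed genes from the wild-type libraries. The 35 members with a mean log2 CPM of 6 or more had a median log2 fold change of 0.553, so the difference was not confined to weakly expressed members. The SE of that median, 0.10, came from resampling genes that share the same 6 libraries. It leaves out the spread between libraries, so this test cannot decide the cause. Low complexity of wild-type library 1 stays open: without it the difference was 0.515 (SE 0.25), within reach of the 0.1 set as the limit. More granulocyte-monocyte progenitors, which are Sca-1-negative and CD34-positive and would be removed by this sort, were not shown by the summed CPM of Mpo, Elane, Ctsg and Prtn3: the knockout libraries, at 60.5, 157.5 and 60.8 (mean 92.9 ± 55.9, SD, n = 3), lay below wild-type libraries 1 and 3 (158.8 and 2067.5) and on both sides of library 2 (117.5). They stay open because members of the sum disagreed. Mpo, at 56.9 to 136.4 CPM in knockout, lay above wild-type libraries 1 and 2 (36.5 and 45.6) and below library 3 (1372.1). Prtn3, at 2.29 to 11.3 CPM in knockout, lay below every wild-type library (70.7 to 367.0), and Elane and Ctsg overlapped between genotypes. More megakaryocyte- and erythroid-primed cells, with the erythroid list at an adjusted p of 0.0665, and an effect of the lost gene on cell cycling also stay open, the last untested.

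The lower immediate early genes may reflect cell handling. Low complexity of wild-type library 1 is argued against by the value without it, -0.579 (SE 0.08). A stronger heat shock response in the wild-type sort stays open, because only 2 heat shock members were tested, with a median of -0.239. Hspa1a and Hspa1b, too low for a test, had 83 and 271 counts in wild-type library 1 and at most 13 in any other. The order in which the animals were processed is not given in the sources used here, and a biological difference between genotypes was not tested.

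Over the 10 ways to divide the 6 libraries into 3 and 3, the real division was the 1 with the most genes by edgeR (1, highest other 0). That gene was Hlf, the targeted gene, so this count follows from the design and says nothing about other genes. The real division also had the most genes by DESeq2 (170, highest other 51). For lists, 2 of the 10 gave as many as the real 7, and the highest other gave 9, from wild-type libraries 1 and 2 with knockout library 1. With 10 divisions no share under 0.05 can be had.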
